A study of Mus musculus with 6 samples.

How the data were processed

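Total RNA of 6 samples (4 iPS lines, 1 ES line and 1 primary hepatocyte culture) was hybridised to 1 mouse 430 array each. The deposited values are signal intensity on a linear scale, never negative, and per the submitters' processing notes the authors made them with MAS5, whose version is not given in the sources used here. The table held 45101 probe sets, of which 64 were controls. The deposited intensity values were not brought to 1 scale between arrays: the medians ran from 17.8 to 34.3 and the means after trimming 2% at each end from 96.5 to 190.3 (ratio 1.97). The hybridisation control BioB, by its middle probe set, ran from 549 to 716.

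The plan written before the data were examined used the values as deposited, on the premise that they had been scaled. That premise did not hold, so the main setting became quantile normalization, planned as an alternative, of the 45037 probe sets that are not controls. This was decided after array medians and correlations between arrays had been seen and before any gene was tested. Numbers of genes called with the values as deposited are given beside the main ones, and so are the list counts and list calls that differed most. In that setting limma estimated no variation of the variance between genes (infinite prior degrees of freedom), against 4.61 in the main setting. Genes of like signal were thus given the same variance, and a gene's own spread over the lines did not count. Its p-values are therefore not comparable with those of the main setting. Values were then taken as log2(signal + 18.5), where 18.5 is the median over arrays of the 40th percentile and also serves as the background level. A fold change on this scale understates the change of dim genes. Where all arrays of 1 side were at or below the level, a ratio is given as at least N-fold: the mean log2 signal of the brighter side against the dimmer side set at the level or its own value, whichever was higher.

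Gene names came from the platform annotation provided with the data, updated by Entrez number through a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 34945 had 1 gene, 932 had several and 9160 had none, and 34741 of the first matched by number. For each of 18193 genes the probe set with the highest mean was kept, and 15370 genes with at least 1 array above the level were tested. Of 960 genes with 2 or more called probe sets against the culture, 6 had calls in both directions. H19 and Ddx3y were not among the genes tested.

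Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on all 6 arrays in 3 groups. The residual spread comes from the 4 lines alone (3 degrees of freedom), and the lone arrays are assumed to vary as the lines do. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. ES and hepatocyte were compared without a test. With 26 gene lists fixed beforehand (581 symbols, 500 tested), set tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Camera and fry p-values were adjusted over the 26 lists. With an estimated correlation, camera had only the few residual degrees of freedom and called no list in any fit. Its lowest adjusted p in the main setting was 0.392 against the hepatocyte array and 0.267 against ES. A list that it did not call is therefore not shown to be unchanged. The procedure was tested on simulated arrays with 200 genes changed by known amounts, 10 runs per comparison. Against the hepatocyte array, 30.0% of genes changed by 2 on the log2 scale were recovered and 3.2 genes per run were called falsely. Against the ES array these values were 32.0% and 2.4. Noise was drawn for each gene on its own, with no shift shared by the genes of an array. In the data 3603 genes were called against the hepatocyte array, far more than the 200 changed here. The simulated recovery therefore does not carry over to that comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

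The genes named were set by a rule fixed beforehand: a list of 21 markers, the 10 largest rises and falls among called genes whose lone array lay outside the range of the lines, the 2 largest members of each list in each direction, the 10 largest ES to hepatocyte differences each way, and the 3 genes per line furthest from the other lines. RIKEN and other model names were passed over among the largest changes. As 0 genes passed against ES, the same rule was applied to the fit without line 4 and to the values as deposited, a choice made after seeing the data. Alternatives were the offset and filter percentile, the scaling, the probe set rule, each line left out, the variance model, a 2-fold minimum and a fit on 2 groups only.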

Results

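Gene expression was measured in 6 mouse cell samples, each on 1 Affymetrix Mouse Expression 430 array, a chip that carries several probe sets for many genes. The labels name 4 of them as protein-based induced pluripotent stem (iPS) lines, numbered 1 to 4, which form 1 group of 4 arrays. A commercial C57/BL6J embryonic stem (ES) line gave 1 array, and a primary culture labelled hepatocyte gave 1 array. Per the labels, hepatocytes were taken from mice at day 13.5 of pregnancy, without saying whether from mother or fetus, and grown with 10 ng/ml epidermal growth factor and 15% serum. The iPS lines were kept on embryonic fibroblast feeders that had been treated with 10 µg/ml mitomycin C. The deposited signals had array medians of 17.8 to 34.3 (ratio 1.93), with line 4 lowest, and were brought to 1 distribution before comparison. A level of 18.5, the 40th percentile of the normalized signal, served as the background level. The number of arrays limits the precision of every value. The labels call the lines separate, but do not say that they came from separate cultures or animals. The p-values therefore measure only the spread among these 4 arrays. The ES and hepatocyte arrays have no replicate, and each was assumed to vary as the lines do.

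The first question was whether the iPS lines resemble ES cells or the starting culture. Across 15370 genes, each of the 4 lines correlated more strongly with the ES array than with the hepatocyte array. The mean Pearson r was 0.956 ± 0.0075 (SD, n = 4) with ES and 0.780 ± 0.0246 (SD, n = 4) with the hepatocyte culture. The ES and hepatocyte arrays correlated at 0.788. Spearman's rho across genes ran from 0.934 to 0.951 between the lines and ES and from 0.729 to 0.784 between the lines and the culture. The mean difference between both Pearson correlations was 0.176 ± 0.0214 (SD, n = 4). An exact two-sided sign test over the 4 lines gave p = 0.125, the smallest this design allows. Genes are not independent replicates, so no test was made across them. The 6 correlations between lines ran from 0.916 for lines 2 and 4 to 0.988 for lines 1 and 3, and those between lines and ES ran from 0.945 to 0.962.

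**Figure D1:**
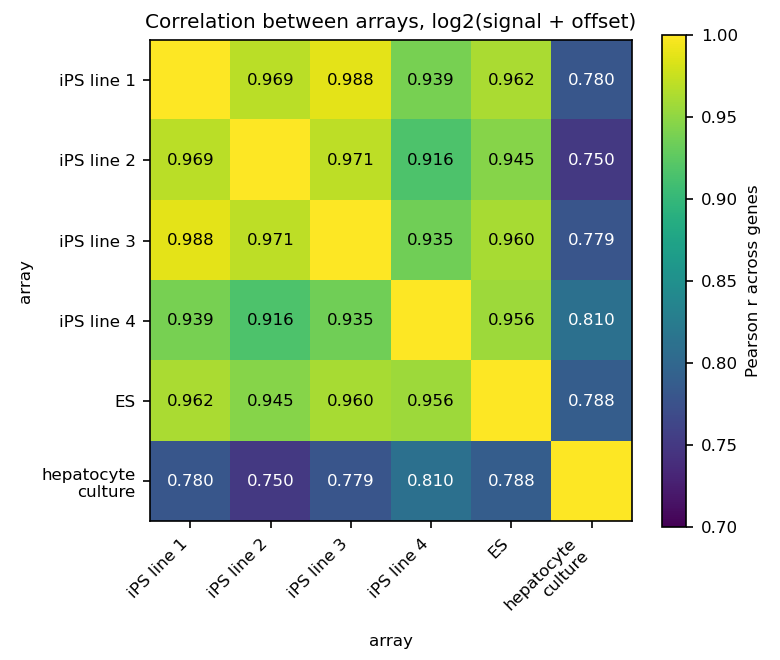
Pearson correlation across 15370 genes between each pair of the 6 arrays, on log2(normalized signal + offset), with the arrays on both axes and r as colour. Pairs among the lines and ES have r of 0.916 to 0.988, and pairs with the hepatocyte culture have r of 0.750 to 0.810.

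Compared with the hepatocyte culture, which the labels give as the starting cells, the iPS lines had higher signal of pluripotency genes and lower signal of connective tissue and macrophage genes. Pou5f1 (Oct4, a core pluripotency factor, chromosome 17) measured 4627 ± 702 (SD, n = 4) in the lines and 12.3, not above background, in the culture, at least 249-fold higher. Nanog measured 3584 ± 519 (SD, n = 4) against 0.488, at least 193-fold higher, and Sox2 measured 5027 ± 715 (SD, n = 4) against 26.0. In the other direction, Col3a1, a fibrillar collagen, measured 80.0 ± 129 (SD, n = 4) in the lines and 8433 in the culture, and Igf2, a fetal growth factor, measured 175 ± 195 (SD, n = 4) against 9473. By limma with Benjamini-Hochberg adjustment, 3603 of 15370 genes passed, 1892 higher and 1711 lower in the lines, and 3449 of these differed at least 2-fold. The culture's array lay outside the range of the lines for 67.1% of genes, where chance gives 40%.

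The fixed pluripotency list had 34 measured members, and 32 rose over all genes tested (34 adjusted over the list alone). Its median difference was 5.02 on the log2 scale and its set test by camera gave an adjusted p of 1.64e-28, and adjusted p = 0.392 with an estimated correlation. In the main setting no list had a lower value against the culture in that last form, which had too few degrees of freedom to separate the lists. Dppa5a, an RNA-binding protein of ES cells, rose by 8.57 ± 0.16 (SE, log2; adjusted p = 6.39e-07). Tdgf1, a Nodal co-receptor, reached at least 370-fold over the background of the culture. Zfp42 (Rex1) measured 3171 ± 666 (SD, n = 4) against 0.433, and Lin28a measured 608 ± 237 (SD, n = 4) against 0.210. Of the reprogramming factors, Klf4 measured 2581 ± 1142 (SD, n = 4) against 902 and did not pass by limma (adjusted p = 0.103, and 0.00579 to 0.332 over the alternatives, the lowest without line 4). Myc fell, with 87.1 ± 35.7 (SD, n = 4) in the lines and 1173 in the culture (adjusted p = 0.00270). Among 13 primed pluripotency genes, 7 rose, with Nodal and Lefty1 the largest, and 3 fell, with Fst and Sfrp2 the largest (camera adjusted p = 0.0567). Among 19 germ line genes, 11 rose, including Tex19.1 and Dppa3, and 1 fell, Tdrd7 (camera adjusted p = 3.76e-06; adjusted p = 0.392 with an estimated correlation). Of 25 epigenetic regulators, 18 rose and 0 fell, with Dnmt3l, a DNA methyltransferase cofactor, at least 117-fold higher and Tet1, a 5-methylcytosine dioxygenase, up by 5.65 ± 0.99 (SE, log2). That list had a camera adjusted p of 9.51e-09, and adjusted p = 0.392 with an estimated correlation.

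Cdh1 (E-cadherin) reached at least 193-fold over the background of the culture. Epcam measured 2729 ± 586 (SD, n = 4) against 3.80, and another of its probe sets 109 to 332 against 51.0, while Dlk1 and Sox9 of the same cholangiocyte and hepatoblast list fell. In all, 5 of the 11 members of that list rose and 2 fell (camera adjusted p = 0.0543). Metabolic and proliferation lists also rose. Of 30 glycolysis and hypoxia genes, 16 rose and 0 fell, led by Pdk1 and the glucose transporter Slc2a3, which rose by 4.54 ± 0.21 (SE, log2). The camera adjusted p was 2.06e-08, and adjusted p = 0.392 with an estimated correlation. Among 24 G2 and M phase genes 11 rose, with Bub1 and Ccnb2 up by 2.05 ± 0.21 and 2.50 ± 0.27 (SE, log2). Among 24 DNA replication genes 8 rose, and among 18 cholesterol synthesis genes 8 rose. The camera adjusted p of these 3 lists was 5.17e-06, 0.00275 and 0.000502. It became adjusted p = 0.398, 0.483 and 0.398 with an estimated correlation. With the values as deposited, the members that rose numbered 5 of 25 for the epigenetic list, 2 of 24 for G2 and M phase, 1 of 24 for replication and 1 of 18 for cholesterol synthesis. Pluripotency genes that rose were then 27 of 34 and glycolysis genes 12 of 30. The replication list was not called by camera with the values as deposited or with median centring.

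Lists of connective tissue, macrophage and interferon genes were lower in the lines. Of 38 fibroblast and feeder stroma genes, 35 fell and 0 rose, with a median difference of -4.50 (log2; camera adjusted p = 9.14e-19; adjusted p = 0.398 with an estimated correlation). S100a4 fell by 6.67 ± 1.38 (SE, log2; adjusted p = 0.0130), and Col1a1 measured 25.3 ± 29.8 (SD, n = 4) against 2440. Of 12 stellate cell and smooth muscle genes 5 fell, among them Acta2 (smooth muscle actin) and Pdgfrb (camera adjusted p = 0.000754; adjusted p = 0.464 with an estimated correlation). On line 4 these genes stood above lines 1 to 3: Acta2 measured 2532 there and 76.9 to 100.0 on lines 1 to 3, and 534 on ES. Of 22 macrophage and leukocyte genes, 18 fell, including Cd14 and Tyrobp, and 1 rose, Laptm5 (camera adjusted p = 1.44e-09; adjusted p = 0.392 with an estimated correlation). Of 30 interferon response genes, 23 fell, and Ifit1 fell by 5.62 ± 0.30 while Ifit3 fell by 5.88 ± 0.42 (SE, log2; camera adjusted p = 1.22e-13; adjusted p = 0.392 with an estimated correlation). Other genes with the largest falls were Ptn, Cav1, Ccl9, Cdh11, Postn, Tm4sf1 and Prss23. Thy1, a surface marker of fibroblasts, fell from 807 to 184 ± 96.5 (SD, n = 4). With fry, which does not compare a list with other genes, the 11 lists called by camera passed, the largest adjusted p being 0.0450. So did 6 lists that camera did not call: primed pluripotency (0.0474), cholangiocyte (0.0124), erythroid (0.0252), trophoblast (0.0124), imprinted (0.0403) and p53 genes (0.0403). With the values as deposited, these 6 did not pass by fry (adjusted p = 0.552, 0.104, 0.552, 0.155, 0.335 and 0.718, in that order). Nor did the G2 and M phase (0.718), replication (0.805), epigenetic (0.246), cholesterol synthesis (0.155) and glycolysis (0.0791) lists. The other lists called by camera still passed by fry, and so did the sex chromosome list (0.0483). Adjusted over the list alone, the numbers that rose and fell were 8 and 3 for primed pluripotency, 14 and 1 for germ line, 18 and 0 for epigenetic, 17 and 0 for glycolysis, 12 and 0 for G2 and M phase, 11 and 0 for replication and 11 and 0 for cholesterol synthesis genes. They were 0 and 37 for fibroblast, 0 and 8 for stellate, 1 and 19 for macrophage and 0 and 25 for interferon genes.

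Of 45 measured members of the hepatocyte list, 3 rose, among them Apoc1 and Apoe, 1 fell, Cebpa, and 41 did not pass (median 0.14, log2; camera adjusted p = 0.580). Albumin (Alb) measured 191 on the culture's array, 660 on ES and 3425 on line 4, against 1.12 to 39.4 on lines 1 to 3. Ttr measured 60.2 on the culture, 151 on ES, 967 on line 4 and 10.5 to 16.1 on lines 1 to 3. Afp, the fetal albumin, measured 23.5 on the culture and 29.4 on line 4, and Hnf4a, a liver transcription factor, measured 9.55 on the culture. Of the other 3 Hnf4a probe sets, 2 measured 5.62 and 4.70 there, and 1 measured 33.4, above background, with 37.8 on ES and 2.89 to 17.6 on the lines. Without line 4 the list gave 4 rises and 14 falls and a mean of -0.44 (log2) in place of 0.23, and was called by camera (adjusted p = 0.0107, and 0.0107 to 0.914 over the alternatives). For that call, adjusted p = 0.243 with an estimated correlation. Of 18 endoderm genes, 1 rose, Amn, and 3 fell, among them Dab2 and Pdgfra. Of 12 endothelial genes, 2 rose, Pecam1 and Tek, and 4 fell, led by Flt1 and Kdr. In mesoderm and neuroectoderm, each with 13 measured genes, 1 rose and 1 fell in the first and 2 rose and 3 fell in the second. Among trophoblast genes 5 of 12 rose, among early embryo genes 1 of 11, and among erythroid genes 1 of 8. The p53 list had 6 rises and 3 falls of 20, the ATF4 amino acid response 6 and 1 of 25, and imprinted genes 6 and 8 of 37. Without line 4, the rises and falls were 3 and 9 for endoderm, 7 and 7 for p53, 7 and 6 for ATF4, 9 and 12 for imprinted and 0 and 4 for sex chromosome genes, and early embryo genes had 4 rises. Camera then called the endoderm list lower (adjusted p = 0.0180), the sex chromosome list lower (0.00633) and the primed pluripotency (0.0154) and early embryo (0.0304) lists higher. With an estimated correlation, adjusted p = 0.258, 0.243, 0.371 and 0.556 for these 4 lists. As deposited, the rises and falls were 2 and 5 for endoderm, 3 and 4 for p53, 3 and 3 for ATF4, 0 and 7 for stellate and 0 and 4 for sex chromosome genes, and early embryo genes had 3 rises. Camera then called the primed pluripotency (0.00459), cholangiocyte (0.000585), trophoblast (0.00320) and early embryo (0.00582) lists higher and the sex chromosome list lower (0.00220). With an estimated correlation, adjusted p = 0.565, 0.421, 0.493, 0.565 and 0.220. Of the 3 maternal transcripts of the Dlk1-Dio3 region 0 passed. Among 5 sex chromosome genes, Xist fell (143 ± 42.9, SD, n = 4, against 2177) and Kdm5d fell, and Eif2s3y, on the Y chromosome, measured 237 on the culture. Adjusted over the list alone, the numbers that rose and fell were 2 and 0 for hepatocyte, 5 and 2 for cholangiocyte, 3 and 4 for endoderm, 4 and 4 for endothelial, 0 and 1 for mesoderm, 3 and 3 for neuroectoderm, 5 and 1 for trophoblast, 0 and 0 for early embryo and 1 and 0 for erythroid genes. They were 6 and 5 for p53, 8 and 3 for ATF4, 6 and 9 for imprinted and 0 and 2 for sex chromosome genes.

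The split of the calls depended on the scaling, and their number on single lines. With the values as deposited, the setting planned before the data were examined, 2738 genes passed, 880 higher and 1858 lower, so that 32.1% rather than 52.5% of calls were higher in the lines, and with median centring 3255 passed, 39.2% higher. The median difference of all genes was 0.08 (log2) after normalization and -0.20 as deposited. Leaving out line 1 or line 3 lowered the count to 2222 or 2198, and leaving out line 4 raised it to 5401.

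**Figure D2:**
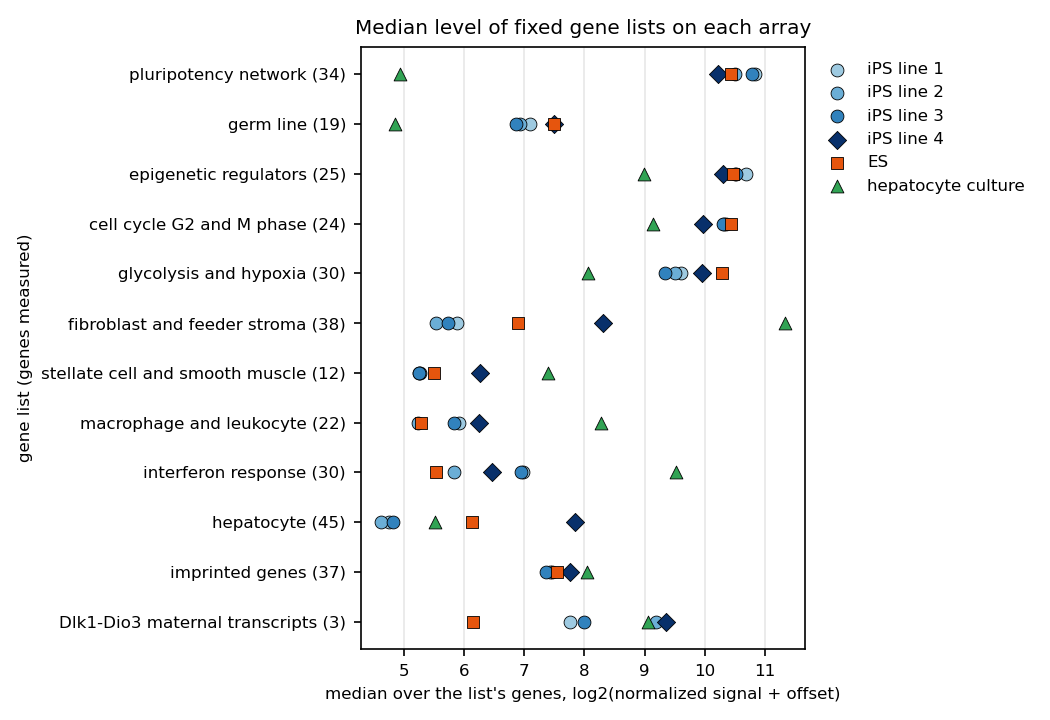
Median over the measured genes of 12 fixed lists on each of the 6 arrays (x axis, log2 of normalized signal plus offset; y axis, list with its number of genes). Line 4 lies between lines 1 to 3 and the hepatocyte culture for fibroblast genes at 8.31, and above every other array for hepatocyte genes at 7.85.

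The iPS lines were next set against the ES array, the reference for a pluripotent cell. Core pluripotency transcripts lay at similar signal: Pou5f1 measured 4627 ± 702 (SD, n = 4) in the lines and 4282 on ES, Nanog 3584 ± 519 against 3970, and Sox2 5027 ± 715 against 5283. Crxos, a homeobox gene, measured 30.8 ± 4.72 (SD, n = 4) in the lines and 503 on ES, although its other probe set measured 17.7 to 27.0 in the lines and 23.2 on ES. Ankrd33b measured 208 ± 66.8 (SD, n = 4) in the lines and 13.2 on ES, while its other 2 probe sets measured 16.3 to 62.8 against 37.5 and 4.62 to 24.0 against 0.979. Meg3, a maternally expressed noncoding RNA of chromosome 12, measured 2143 ± 1029 (SD, n = 4) in the lines and 203 on ES. By limma, 0 of 15370 genes passed, 683 had an unadjusted p below 0.05, and the smallest adjusted p was 0.109, for Crxos. The ES array lay outside the range of the 4 lines for 39.0% of genes, where chance gives 40%. That range includes line 4, which stood apart from the other lines and widens the range where it is outlying. The share was not computed without line 4, so its nearness to chance does not show that ES is like the other lines. In simulated arrays of the same design, limma recovered 1.2% of genes changed by 1 on the log2 scale, 32.0% of those changed by 2 and 82.0% of those changed by 4, so most differences of 2 or less were not detectable. On average 2.4 genes per simulated run were called falsely. The simulation held no shift shared by the genes of an array, so these rates do not cover one.

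The call of 0 depended on the scaling and on line 4. With the values as deposited, the planned setting, 26 genes passed, 10 higher and 16 lower in the lines. That fit ignored each gene's own spread over the lines, so its adjusted p-values are not comparable with the others. Alb passed there as lower in the lines (limma adjusted p = 0.00331), although its normalized signal was 3425 on line 4 and 660 on ES. Without line 4, 76 passed, 35 higher and 41 lower, and 19 genes were shared between both sets of calls. The genes that follow passed in at least 1 of these sets, and their values are over all 4 lines unless given by line. Peg3, an imprinted zinc finger gene, measured 2750 ± 1114 (SD, n = 4) in the lines and 261 on ES (adjusted p = 0.516 over all 4 lines, 0.00635 without line 4 and 0.00151 as deposited, the range over the alternatives being 0.00151 to 1.00). Hprt, on the X chromosome, measured 4475 ± 1386 (SD, n = 4) against 670 (adjusted p = 0.376, 0.0197 without line 4 and 0.00921 to 0.963 over the alternatives). Lefty2 measured 707 ± 438 (SD, n = 4) against 61.9, with 158 on line 4. Olig2 measured 107 to 199 on lines 1 to 3, 0.633 on line 4 and 1.03 on ES, and Zfp874a measured 192 to 215 on lines 1 to 3, 7.81 on line 4 and 4.57 on ES. In the other direction, P2rx3 measured 7.57 ± 4.84 (SD, n = 4) in the lines and 159 on ES, Efhc2 23.3 ± 7.50 against 280, and Rpl39l 316 ± 152 against 2139. The germ cell genes Dazl and Khdc3 measured 137 ± 120 and 211 ± 161 (SD, n = 4) in the lines and 595 and 1073 on ES, with line 4 nearest to ES at 316 and 449.

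No member of any list passed over all genes tested. Adjusted over the list alone, 3 of the 3 Dlk1-Dio3 maternal transcripts rose: Meg3, Rian with 408 ± 223 (SD, n = 4) against 52.6, and Mirg with 113 ± 51.2 against 5.75. Their median difference was 2.42 (log2; camera adjusted p = 5.13e-07; adjusted p = 0.267 with an estimated correlation). In the main setting no list had a lower value against ES in that last form, which called no list. Over the imprinted list, 6 of 37 genes rose by the test over the list alone, and the median was 0.24. Its camera adjusted p was 0.00159, and adjusted p = 0.267 with an estimated correlation. By fry the adjusted p was 0.00799, and 0.906 with the values as deposited. The imprinted list includes Meg3, Rian and Mirg, so its calls are not independent of those for the Dlk1-Dio3 transcripts. It was not tested without these 3. Phlda2 and Peg3 were among its largest differences. Cldn4 and Cldn7 were the largest of 11 cholangiocyte and epithelium genes, of which 3 rose by the list test (camera adjusted p = 0.00122; adjusted p = 0.267 with an estimated correlation). Dppa3, an oocyte and ES cell factor, rose among 34 pluripotency genes by the list test, with 556 ± 37.4 (SD, n = 4) against 145, and that list as a whole had a median of -0.05 (camera adjusted p = 0.952).

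The ATF4 amino acid response list was lower in the lines, with 5 of 25 genes falling by the list test and a median of -0.64 (log2; camera adjusted p = 3.89e-07; adjusted p = 0.662 with an estimated correlation). Chac1 measured 113 ± 31.2 (SD, n = 4) in the lines and 437 on ES, and Psph 553 ± 131 against 1621. Glycolysis and hypoxia genes had a median of -0.35 (camera adjusted p = 0.000102; adjusted p = 0.662 with an estimated correlation), with Ddit4 at 999 ± 259 (SD, n = 4) against 2558. Interferon response genes had a median of 0.56 (camera adjusted p = 1.32e-05; adjusted p = 0.681 with an estimated correlation), and Rtp4 spread from 10.5 to 299 over the lines against 0.934 on ES. Macrophage genes had a median of 0.25 (camera adjusted p = 0.0407; adjusted p = 0.863 with an estimated correlation, and 0.219 without line 4). By fry, the imprinted list passed, though not with the values as deposited, and the other 6 lists called by camera did not pass. Hepatocyte, fibroblast, stellate and endoderm genes were not called with all 4 lines, but were lower than on ES by camera without line 4 and with the values as deposited. With an estimated correlation, adjusted p = 0.225, 0.225, 0.316 and 0.291 without line 4, and 0.648, 0.827, 0.648 and 0.648 as deposited. Without line 4, 10 of 45 hepatocyte, 2 of 38 fibroblast, 1 of 12 stellate and 2 of 18 endoderm genes fell. Primed pluripotency genes were called higher under the same 2 settings (adjusted p = 0.429 and 0.748 with an estimated correlation). Germ line and replication genes were called lower as deposited (adjusted p = 0.648 and 0.827 with an estimated correlation). None of these 7 lists was called with median centring. The fibroblast list had a median of 6.90 (log2 of signal plus offset) on ES, 8.31 on line 4 and 5.53 to 5.89 on lines 1 to 3.

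**Figure D3:**
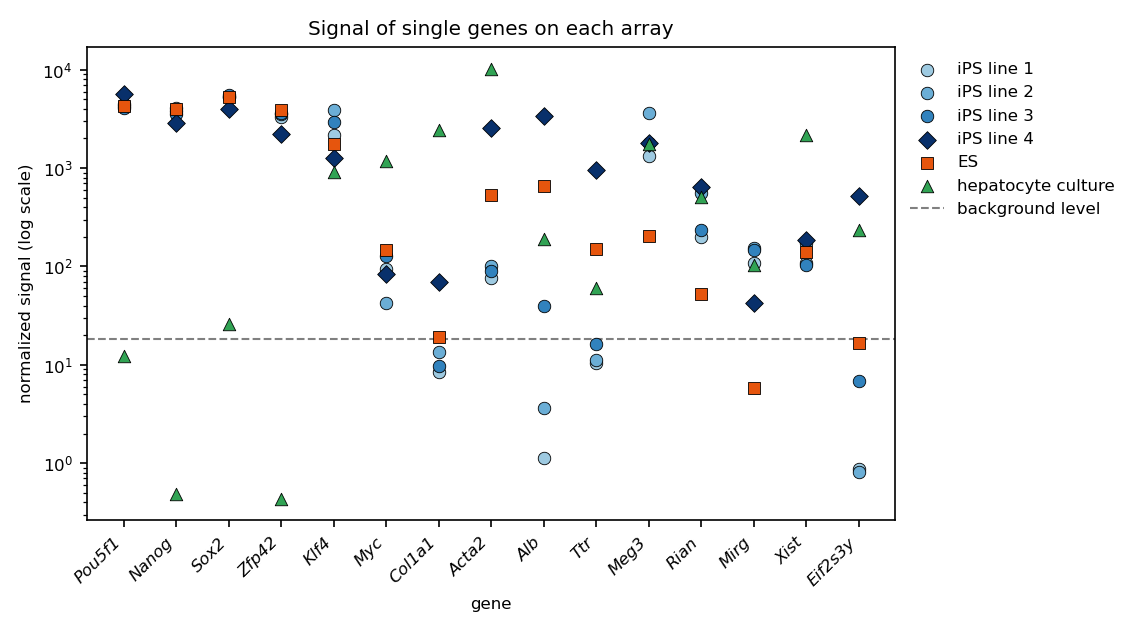
Normalized signal (log axis) of 15 genes on each of the 6 arrays, 1 point per array, with the background level dashed. For Pou5f1, Nanog and Sox2 the ES array lies within the range of the lines, Meg3 is lowest on ES at 203, and Alb is highest on line 4 at 3425.

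Taken as single arrays, ES cells and the hepatocyte culture differed at least 4-fold in 1598 of 15370 genes, 734 higher on ES and 864 higher on the culture, with no replicate check and no p-value. Among the 10 genes with the largest differences towards ES on the offset scale, Dppa5a (8.48, log2), Sox2 (6.90) and Rhox5 (6.44) were above background on both arrays. The other 7 were not above background on the culture and have no order among them. Tdgf1 was at least 558-fold higher on ES, Pou5f1 at least 232-fold, Nanog at least 215-fold and Zfp42 at least 210-fold, and Trap1a, Cdh1 and Mymx at least 183-fold, 169-fold and 154-fold. Towards the culture, Col3a1 (-7.31, log2), Cav1 (-6.80), Ccl9 (-6.79) and Ifi202b (-6.34) were above background on both arrays. On ES, Ifit3, Rtp4, Cyp1b1, Ccl5 and Ifit1 were not above background, and were at least 140-fold, 127-fold, 124-fold, 123-fold and 108-fold higher on the culture. Ptn measured 3593 and 1209 on the culture by 2 probe sets, against 2.18 and 2.19 on ES, while the third measured 45.9 and 42.2. Among 10000 random lists of like expression, the ES minus culture median lay at percentile 100 for pluripotency genes (5.15) and at percentile 0 for fibroblast (-4.12), macrophage (-2.55) and interferon (-3.19) genes. The hepatocyte list median was 0.70 higher on ES, at percentile 100. The lines differed from ES at least 4-fold in 85 to 134 genes and from the culture in 1437 to 1832.

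The position of each line between ES and the culture was expressed on a scale with ES at 0 and the culture at 1. The scale does not separate a change in the cells of a line from RNA of other cells, such as the fibroblast feeders. Over the 864 genes higher in the culture, the lines had a median position of 0.0461 ± 0.111 (SD, n = 4), where line 4 lay at 0.207, and the mean without line 4 was -0.00772. Simulated lines without any difference from ES gave 0.0506, with a range of 0.0349 to 0.0646. The simulation drew noise for each gene on its own, from the spread over all 4 lines. It held no shift shared by the genes of 1 array, so its ranges are too narrow to judge the lines by. Over the 734 genes higher in ES, the position was 0.0779 ± 0.0203 (SD, n = 4), against 0.0525 (0.0415 to 0.0661) in simulation. It was 0.164 with the values as deposited and 0.152 with median centring. The hepatocyte list lay 0.95 to 1.19 (log2) below ES on lines 1 to 3 and 1.59 above it on line 4, and the fibroblast list 0.67 to 0.81 below and 1.23 above.

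Among the lines, line 4 stood apart. It exceeded each other line at least 4-fold in 146 genes and fell short of each in 18, where line 2 had 0 and 2 and lines 1 and 3 had 0. The genes furthest from the other lines on line 4 were the liver transcripts Alb, Fabp1 (1312 against at most 5.70) and Serpina1c (1446 against at most 11.1). On line 2 they were Ifi27, with 20.2 against 411 to 813, Wfdc17 and Ctss, the first an interferon-induced gene. Taken in turn as the single array against the other 4 pluripotent arrays, line 4 gave 44 genes by limma and line 1, line 2, line 3 and ES gave 0 each, with 2210, 104, 1812, 97 and 684 genes at an unadjusted p below 0.05. ES ranked 3 of 5 by that number. In the fits for lines 1 to 3 and ES, the outlying line 4 was in the group of 4 and added to its spread. The counts of 0 are therefore not on equal terms with the 44 of line 4. As deposited, ES gave 24 genes, and the lines were not counted in that setting. The Y-linked gene Eif2s3y measured 525 on line 4, at most 6.85 on lines 1 to 3 and 16.7 on ES. As a measure of RNA quality, the ratio of 3' to 5' beta-actin probe sets was 2.57 on line 2, 1.90 on line 4, 1.82 on ES, 1.48 and 1.51 on lines 1 and 3 and 1.22 on the culture. For Gapdh it ran from 0.794 on the culture to 1.04 on line 2. The middle probe set of 18S ribosomal RNA measured 9404 on ES, 4691 on line 4 and 1396 to 2116 elsewhere.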

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

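The tests of explanations in this part were chosen after the results they address had been seen. Within the 4 iPS lines, 192 values (156 named genes, 26 list medians and 10 measures of arrays) were examined for a line whose gap to the next, divided by the range, exceeded Dixon's critical value, and 38 did. Line 4 accounted for 32 of the 38, line 2 for 3, and lines 1 and 3 for 3. Chance gives about 1 in 20, but this count cannot be set against that rate, since 30 of the 156 genes were named for their distance between lines or from the fit without line 4, and 9 of these 30 exceeded the value. Of the other 126 named genes 21 did, 19 of them on line 4. Over all 15370 genes tested, a count added after the result was seen, 1406 did (9.15%), 798 on line 4, 448 on line 2, 74 on line 1 and 86 on line 3. Genes are not independent of each other.

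On line 4 the ratio of gap to range was high for liver and endoderm genes: Fabp1 0.942, Serpina1c 0.926, Ttr 0.950, Cubn 0.979, Aass 0.893 and Dab2 0.839. It was high for stromal genes: Acta2 0.934, Col1a1 0.860, Col1a2 0.872, Col3a1 0.966, Cdh11 0.853, Prss23 0.858, Tm4sf1 0.909 and Igf2 0.847, and for Psph 0.904 and the Y-linked Eif2s3y 0.918. Lower on line 4 were the X-linked Ebp 0.911, Nsdhl 0.844 and Trap1a 0.920, and Epcam 0.842, Lefty1 0.861, Olig1 0.836, Pdk1 0.860 and Zfp874a 0.954. The list medians of line 4 stood out for hepatocyte 0.938, fibroblast 0.870, stellate 0.988, endoderm 0.863 and sex chromosome genes 0.845 (all higher) and for G2 and M phase genes 0.899 (lower). So did its position over genes higher in ES, 0.840, and its low deposited median, 0.893. On other lines, Cth 0.855, Ctss 0.921 and Ooep 0.887 were low on line 2, Dhh 0.868 and Rgs11 0.844 low on line 1 and Tmem125 0.880 high on line 3.

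The first pattern is the liver signal of line 4, on which 44 of 45 hepatocyte-list genes exceeded the culture itself. As the source of this liver signal, carry-over of cells like those on the culture's array is argued against. The median excess of line 4 over that array was 2.33 (log2, quartiles 1.38 and 3.15). For stromal genes, neither carry-over nor RNA of the fibroblast feeders was tested. The fibroblast list median was 8.31 on line 4, 5.53 to 5.89 on lines 1 to 3 and 11.3 on the culture (log2 of signal plus offset). A single liver-like RNA source on the line 4 and ES arrays could give 1 ratio across genes. Over 26 genes the line 4 to ES ratio of the excess over the other lines ran from 1.62 to 12.2 (median 6.49), with an SD of 0.737 (log2), between the bounds of 0.5 and 1 set for and against it, so this stays open. Differentiation towards liver within line 4 also stays open: Afp measured 29.4 there, near the background level of 18.5, but mature liver cells can lack it.

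The second pattern is lower X-linked signal on line 4 and ES. The fit without line 4 thus set lines of higher X-linked signal against ES. Among 228 X-linked genes with a mean signal above 200, the median shift against each of lines 1 to 3 was -0.83 to -0.72 (log2) on line 4 and -0.77 to -0.73 on ES, while medians of 19 autosomes lay between -0.14 and 0.33. Scaling is argued against, since the X-linked median minus the lowest autosome median was -0.623 (log2) or lower under each of 3 scalings. The X-linked shift itself depended on the scaling: with median centring, it was -0.20 on line 4 and -0.10 on ES against line 2, while autosomes there lay at 0.46 or above. Cells like the culture mixed into line 4 are argued against by a shift of -0.601 or lower (log2) among 96 to 99 X-linked genes with like signal on the culture's array. A candidate explanation is fewer active X chromosomes in line 4 and ES than in lines 1 to 3, for which the shift nearest to 0 was -0.717 after quantile normalization. The Y-linked Eif2s3y measured 525 on line 4, at most 6.85 on lines 1 to 3 and 16.7, not above background, on ES. Kdm5d measured 35.5 on line 4 and at most 12.0 on lines 1 to 3, while Usp9y measured 2.87 on line 4 and 1.66 to 22.4 on lines 1 to 3. Whether line 4 differs in sex from lines 1 to 3 was not tested.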

How the results depend on the processing

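The values as deposited were the planned setting, and became an alternative after array medians and correlations had been seen. The other alternatives were fixed before the data were examined. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The count against ES (0) became 26 as deposited, 4 with the offset at the 60th percentile, 1 with median centring and 1 with every probe set tested on its own, and 0 to 76 with 1 line left out. ES as the lone array (0) gave 24, 1, 1 and 1 under the same 4 settings. The count against the hepatocyte culture (3603) ran from 2198 to 5401 with 1 line left out and was within 1.5 times under the other settings. The ES to hepatocyte count at 4-fold (1598) was 898 with the offset at the 60th percentile and 2687 over single probe sets, which outnumber genes. Genes setting line 4 apart (164) numbered 274 and 85 with the offset at the 20th and 60th percentile. The correlation difference (0.176) was 0.138 without a filter, 0.269 with the 60th percentile filter and 0.146 over single probe sets, in the same direction each time. The position over genes higher in the culture (0.0461) ran from -0.00772 to 0.0760 with 1 line left out. Over genes higher in ES (0.0779) it was 0.164 as deposited and 0.152 with median centring. The mean of the hepatocyte list against the culture (0.23, log2, not called) ran from -0.44, called, without line 4 (adjusted p = 0.243 with an estimated correlation) to 0.47 without line 2. Unless stated, the cause was not tested. Of the alternatives for named genes against the culture, 94 lost and 38 gained a call and 1583 kept their side; against ES 54 gained one. For lists, 13 lost and 24 gained a call against the culture and 1 changed sign with a call (hepatocyte genes without line 4), and 17 lost and 13 gained one against ES. Genes near the level of 18.5 have no reliable order.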

Other observations

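The tests in this part were chosen after the results were seen. Interferon genes differed between the pluripotent arrays: the list median was 6.98 and 6.95 (log2 of signal plus offset) on lines 1 and 3, 6.47 on line 4, 5.83 on line 2 and 5.54 on ES. Rtp4 measured 299 and 265 on lines 1 and 3 and 10.5 on line 2, and 81.0 on line 4. Rsad2 measured 285 and 218 on lines 1 and 3, 111 on line 2 and 42.4 on line 4, the lowest of the lines. The macrophage list median was also lowest on line 2 and ES, at 5.23 and 5.28, against 5.91, 5.83 and 6.26 on lines 1, 3 and 4. The ratio of 3' to 5' beta-actin probe sets, a measure of RNA quality, was highest on line 2 at 2.57, with 1.82 on ES and 1.90 on line 4, against 1.48 and 1.51 on lines 1 and 3. The cause was not tested. Early embryo genes had a list median of 6.09 on ES, 5.92, 5.82 and 5.47 on lines 1 to 3 and 4.92 on line 4, and Calcoco2 of that list measured 790 on line 4, 560 on ES and 106 to 165 on lines 1 to 3.

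The third pattern is the array labelled hepatocyte, on which Col1a2 (9840), Acta2 (10292) and Igf2 (9473) were high while Alb measured 191, and which held both Xist (2177) and the Y-linked Eif2s3y (237). A swap with one of the other 5 arrays is argued against, since the pluripotency list median on this array minus the lowest of theirs was -5.29 (log2), while a swap with an outside sample stays open. Hepatocytes alone that lost liver expression also stay open. Macrophage genes had a median excess over the highest pluripotent array of 2.16 (log2, quartiles 0.885 and 2.85). The pattern was seen in that list, so this excess is part of it and no separate test. Stromal cells and macrophages in the culture stay open. The fibroblast, macrophage and stellate lists exceeded the highest pluripotent array by 2.78, 2.16 and 1.15 (medians, log2), but the pattern was seen in these lists, so their excess does not test it. The erythroid list had its lowest median on the culture, 4.93 against 5.33 to 5.60 on the other arrays (log2 of signal plus offset), with 2 of 8 genes above the level. Cells that changed type in culture were not separated from cells present at the start.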
